A study of Mus musculus with 6 samples.

How the data were processed

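The series holds 6 bulk RNA-seq libraries of mouse dorsal root ganglia, 3 from Ash1l+/- mice and 3 from littermate wild types, grouped by the sample titles. Per the labels' protocols, ganglia were frozen in liquid nitrogen, RNA was extracted with Trizol, and libraries were made with a NEBNext Ultra RNA kit. The kit as named does not mark strand, so reads of overlapping and antisense genes cannot be told apart. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, which may be partly technical.

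The authors deposited raw read counts for 54532 genes, with gene names, positions, lengths and biotypes in the same table. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with GRCm38 (mm10); their parameters are not given in the sources used here. The authors also deposited FPKM values for the same genes. Recomputed from the counts and gene lengths, the FPKM equal the counts divided by 1 effective library size per sample, which was 0.75 of the count total for WT replicate 2 and 1.02 to 1.04 times the total in the other libraries. They therefore hold no measurement beyond the counts and served as an alternative scale. Every entry carries a gene identifier, and 105 symbols occur more than once, so genes were followed by identifier.

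Total counts were 19033437, 17648407 and 18389787 for WT replicates 1, 2 and 3 and 20545722, 17647095 and 17209294 for Ash1l+/- replicates 1, 2 and 3. TMM factors were 1.07, 0.759 and 1.05, and 1.06, 1.06 and 1.05, in the same order. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom between counts of 2 libraries was 3.91.

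From the counts, genes were kept by filterByExpr and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the genotype as the only term and Benjamini-Hochberg adjustment at 0.05 over all genes tested. SEs are the log2 fold change divided by the square root of the F statistic. Gene lists, 21 functional or quality lists and 16 cell type marker lists, were fixed before the data were examined. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted within each of the 2 families, with an estimated correlation and fry beside it. The estimated correlation ended every camera call in the comparisons with 6 libraries and with 5. The directional test of fry called 0 lists with 6 libraries and 8 functional lists with 5. With GC and length trends removed, it called 0 lists in either comparison. fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Of 801 listed symbols, 800 were in the table.

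The functional lists were peptidergic nociceptor, non-peptidergic nociceptor, itch neuron, mechanoreceptor and proprioceptor, cold-sensing neuron, voltage-gated channel, axon injury and regeneration, immediate early, microRNA processing and let-7 host, let-7 target, extracellular vesicle release, synaptic release machinery, H3K36 and Polycomb-Trithorax chromatin, Hox, interferon response, cytokine and innate sensing, cholesterol synthesis, oxidative phosphorylation, mitochondrial genome, cytosolic ribosome, and dissociation and heat stress. The marker lists covered sensory neurons, glia, fibroblasts, vascular, immune and blood cells, neighbouring tissues and dividing cells.

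Genes named in the text followed a rule fixed before the data were examined. Ash1l was always given. With fewer than 10 genes past the threshold, the rule took the 10 protein-coding genes with a mean CPM of at least 1 and the smallest unadjusted p in each direction. With more, it took protein-coding genes past the threshold with a mean CPM of at least 1, a symbol other than a Gm or Rik number and no overlap between groups, choosing the 12 largest rises, the 12 largest falls and the 3 smallest p in each direction. The second form was applied to the 5 libraries. Some genes that the rule selected are not reported here. Members of lists were taken by largest fold among those past the threshold. Gal, Hspb1, Ifi27, Gfra3, Nefh and the Hox paralogs in the plot of Hox genes were chosen after their values were seen.

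The comparison without WT replicate 2 was planned as 1 of 6 leave-one-out fits, and its use beside each result was chosen after seeing the data, as was the removal of GC and length trends. For that removal, a loess curve of each library's log2 CPM deviation on gene length and on the GC share of the longest transcript in GENCODE M21 (span 0.3, values clipped at the 1 and 99 percentiles) was entered as an offset. GC values were found for 99.9% of tested genes. Other alternatives were RLE and upper-quartile factors, library totals, no count filter, a filter of CPM 1 in 3 libraries, DESeq2 1.42.0, limma-voom with and without library quality weights, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean of at least 0.5 or no filter, protein-coding genes only, and omission of sex-linked genes. That omission does not adjust the other genes for sex, which was a term in no fit.

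Scripts were tested on simulated data before use. Counts were drawn for the real genes, and 200 genes were changed by known folds. The spread of each gene was estimated from the real libraries and was the same in every simulated library. No simulated library was set apart as WT replicate 2 is, so the 6-library rates do not measure power in the real data. For 6 libraries and 16032 genes, 30% of the genes changed 4-fold and 0% of those changed 2-fold were recovered, with 2 false calls among 32. For the 5 libraries and 16395 genes, 100% and 87% were recovered, with 11 false calls among 198. With a GC and length trend added to the simulated Ash1l+/- libraries, false calls in the 5-library case numbered 7429 without and 12 with trend removal. With 6 libraries they numbered 7 and 0. After removal, 188 of the 200 changed genes were recovered with 5 libraries and 4 with 6. The added trend was built from the gene lengths and GC values that the removal uses, so this cannot show that the real trends were fully removed.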

Results

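Bulk RNA sequencing was performed on dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, from Ash1l+/- mice and from wild types of the same litters. Each genotype had 3 libraries, named here WT replicates 1 to 3 and Ash1l+/- replicates 1 to 3. Total gene counts ranged from 17209294 in Ash1l+/- replicate 3 to 20545722 in Ash1l+/- replicate 1. Values per gene are CPM, counts relative to library size, after trimmed mean of M-values (TMM) scaling, given as mean ± SD over 3 libraries unless a single library is named. Fold changes compare the libraries labelled Ash1l+/- with those labelled wild type.

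Ash1l encodes a histone H3 lysine 36 methyltransferase and lies on chromosome 3 from 88950622 to 89079375 on the plus strand of GRCm38 (ENSMUSG00000028053). Its transcript was not lower in the libraries labelled Ash1l+/-. CPM was 60.9, 30.9 and 54.4 in WT replicates 1, 2 and 3 and 66.5, 66.5 and 68.9 in the Ash1l+/- replicates. The group values were 48.7 ± 15.7 in WT and 67.3 ± 1.40 in Ash1l+/- (SD, n = 3). The log2 fold change was 0.46 with an SE of 0.27 and an adjusted p of 0.396 in edgeR's quasi-likelihood test. A two-sided exact permutation test of log2 CPM gave p = 0.1, the smallest that 3 libraries against 3 can give. Without WT replicate 2 the log2 fold change was 0.22 (SE 0.08, adjusted p = 0.0593), and removing the libraries' GC and length trends took it to -0.03 (adjusted p = 0.842). The allele structure is not given in the sources used here, so reads over the whole gene need not follow the number of working copies. These counts do not check the labels, so mixed-up labels are not excluded, and the direction of every fold change rests on the labels alone.

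The comparison of the 2 genotypes asked which genes differ in sensory ganglia when 1 Ash1l copy is altered. Among the genes with the smallest unadjusted p, Atf3, a transcription factor induced in injured sensory neurons, was at 26.7 ± 8.14 CPM in Ash1l+/- against 8.20 ± 2.48 in WT, with every Ash1l+/- library above every WT library. Snrpf, a core protein of the spliceosome, was at 2.95 ± 0.561 against 15.3 ± 7.33 CPM. Cytl1, a secreted cytokine-like protein, was at 0.302 ± 0.101 against 1.82 ± 0.239 CPM. Their log2 fold changes were 1.70 (SE 0.32), -2.37 (SE 0.38) and -2.55 (SE 0.37), with unadjusted p of 0.00157, 0.000738 and 0.00042. None of these passed the adjusted threshold in edgeR with all 6 libraries, where the smallest adjusted p was 0.385. DESeq2 called these 3 genes and no other, with adjusted p of 0.0201 for Atf3, 0.000513 for Snrpf and 0.0208 for Cytl1. Atf3 lies on chromosome 1 from 191170296 to 191218039, Snrpf on chromosome 10 from 93583029 to 93589706 and Cytl1 on chromosome 5 from 37735519 to 37739820.

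With all 6 libraries, edgeR called 0 of 16032 genes at an adjusted p of 0.05. At an unadjusted p of 0.05, 1702 genes passed, against 801.6 for a uniform p, and 908 passed with GC and length trends removed. At an unadjusted p of 0.01, 123 passed, against 160.3 for a uniform p. limma-voom called 0 genes and DESeq2 called 3, while voom with library quality weights, added after seeing the data, gave WT replicate 2 a weight of 0.0274 and called 4179. The other genes with the smallest p and higher values in Ash1l+/- were BC005561, Cep290, Yes1, Slitrk2, Loxl2, Ppig, Rgs9, AW011738 and Casp12, with log2 fold changes from 0.64 for Ppig to 1.20 for Rgs9. Cep290, a protein of the ciliary transition zone, was at 21.4 ± 2.26 against 11.5 ± 1.85 CPM. Those with lower values included Prdm8, Plppr3, Tmem158, Tinagl1, Mrps34 and C1ql4, with log2 fold changes from -0.87 for Tmem158 to -1.13 for Mrps34. Tmem158 was at 86.1 ± 7.64 against 157 ± 22.2 CPM. All genes named here missed the adjusted threshold in edgeR with all 6 libraries, and all passed in voom with quality weights. With GC and length trends removed from the 6 libraries several folds shrank, from -0.87 to -0.09 for Tmem158, from 0.64 to 0.09 for Ppig and from 0.89 to 0.31 for Cep290. Simulated counts with the spread of these 6 libraries gave calls for 30 of 100 genes changed 4-fold and for 0 of 100 changed 2-fold. Every simulated library had the same spread and none was set apart as WT replicate 2 is. These rates therefore do not measure power in the real data.

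WT replicate 2 stood apart from the rest. Its log2 CPM correlated with the other libraries at 0.846 to 0.877 across genes, while the other 5 libraries correlated with each other at 0.981 or above. Genes are not independent replicates in these correlations. Messages of the cytosolic ribosome took 5.0% of its counts against 1.17% in each of the other wild types, and the median ribosomal gene was 2.53 higher on the log2 scale than in them. Nuclear genes of oxidative phosphorylation were 2.23 higher by the same measure. The mitochondrial protein genes went the other way, at 0.424% of counts against 1.59% and 1.96%. Across 14128 protein-coding genes, the difference from the other wild types followed gene length with a Spearman rho of -0.46, compared with -0.08 between WT replicates 1 and 3. Median log2 differences of marker lists from the other wild types were 3.18 for skeletal muscle, 1.35 for neutrophil and mast cell, 1.18 for erythrocyte and -1.0 for central nervous system tissue.

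**Figure D1:**
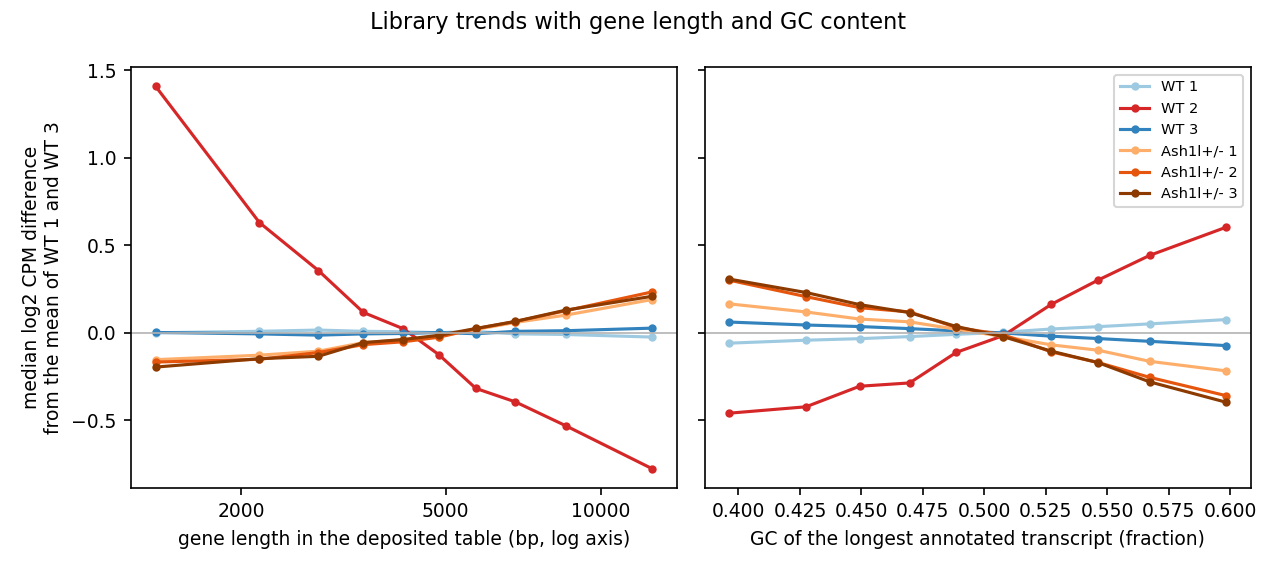
Median log2 CPM difference of each library from the mean of WT replicates 1 and 3, in 10 bins of protein-coding genes by gene length (left, base pairs, log axis) and by GC fraction (right). Lines join the bins of 1 library. WT replicate 2 runs from 1.41 in the shortest genes to -0.78 in the longest, and the Ash1l+/- libraries fall from 0.16, 0.30 and 0.31 at low GC to -0.22, -0.36 and -0.40 at high GC.

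Without WT replicate 2, a planned leave-one-out fit whose use beside each result was chosen after seeing the data, edgeR called 3252 of 16395 genes, 1539 higher and 1713 lower in Ash1l+/-. Of these, 181 differed by at least 2-fold. The 3 Ash1l+/- libraries also differed from WT replicates 1 and 3 along GC content, with a Spearman rho of -0.61 across genes, and along gene length, with a rho of 0.37. GC trends were also present within groups, with a rho of 0.39 between WT replicates 1 and 3 and of 0.44 between Ash1l+/- replicate 1 and the other Ash1l+/- libraries. With both trends removed from each library, 1184 genes passed, 439 higher and 745 lower. Between these 2 analyses of the 5 libraries, 793 genes were called in both in the same direction. Leaving out any other single library from the 6 left 0 genes called. From the 5, leaving out WT replicate 1 as well gave 796 genes with a single wild type left, Ash1l+/- replicate 2 gave 1855 and Ash1l+/- replicate 3 gave 2120.

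**Figure D2:**
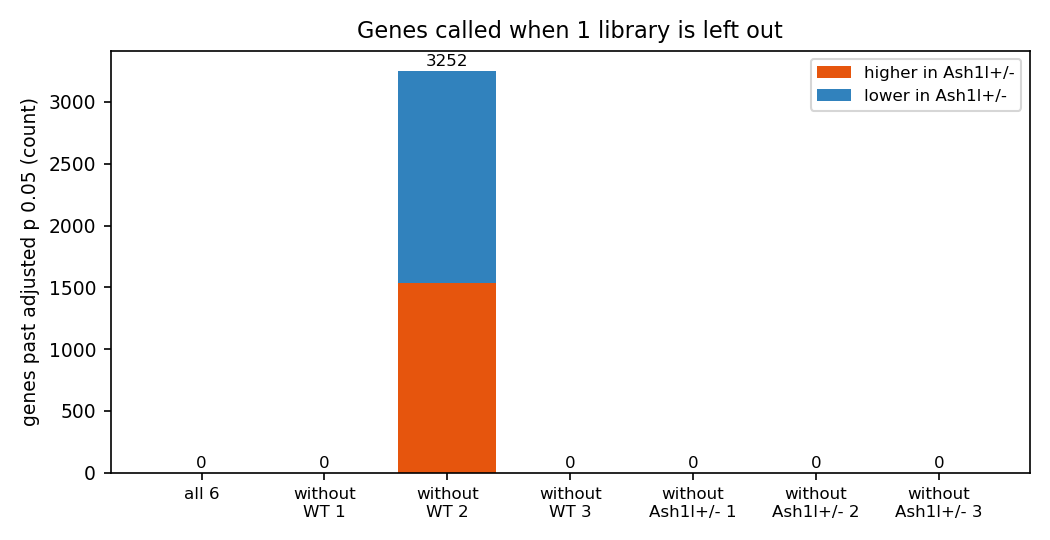
Number of genes past an adjusted p of 0.05 in edgeR with all 6 libraries and with each library left out in turn, stacked as higher or lower in the libraries labelled Ash1l+/-. The count is 3252 without WT replicate 2 and 0 in every other bar.

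Without WT replicate 2, the 5 largest rises among the genes selected by the naming rule were all members of the axon injury list, Sprr1a, Npy, Cckbr, Ecel1 and Atf3. Sprr1a, a small proline-rich protein induced in axotomised neurons (chromosome 3, 92483952 to 92485895), had 814 reads over the 3 Ash1l+/- libraries and 1 over WT replicates 1 and 3, a ratio of 551 with a 95% counting interval from 98.7 to 21805. Npy, the neuropeptide Y gene, had 130 reads against 1, a ratio of 88.1 (15.5 to 3505). Cckbr, a cholecystokinin receptor, had 176 against 2, a ratio of 59.6 (16.3 to 496). These intervals cover counting error only. In WT replicate 2, Sprr1a was at 11.3, Npy at 1.05 and Cckbr at 1.05 CPM. The Ash1l+/- libraries ranged from 6.23 to 23.6 for Sprr1a, 1.05 to 3.27 for Npy and 1.97 to 4.35 for Cckbr. Ecel1, a neuronal endopeptidase, was at 8.64 ± 3.93 CPM in Ash1l+/-, 0.642 and 0.415 in WT replicates 1 and 3, and 4.41 in WT replicate 2. Its log2 fold change over the 5 libraries was 4.0 (SE 0.39, adjusted p = 5.02e-06), against 2.29 (SE 0.92, adjusted p = 0.385) with all 6. Atf3 was higher by 1.97 (SE 0.19, adjusted p = 4.92e-06).

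Other rises in the 5 libraries selected by size were Nts, which encodes neurotensin, at 1.83 (SE 0.19), the chemokine gene Ccl2 at 1.58 (SE 0.40), the receptor gene Gpr151 at 1.45 (SE 0.33), and Tnc, which encodes the matrix protein tenascin C, at 1.30 (SE 0.27). Slfn9, Zkscan16 and Ptprq completed the group, with log2 fold changes of 1.43, 1.31 and 1.24. The largest falls were in Cytl1 at -2.52 (SE 0.45) and Snrpf at -1.91 (SE 0.18), followed by Mfap4 at -1.89, Slc39a5 at -1.62, Mapkapk5 at -1.52, Slirp at -1.50, Pcsk4 at -1.36, Ramp3 at -1.35, Rpl22l1 at -1.30, Apobr at -1.28, Mobp at -1.28 and Nmur1 at -1.27. The smallest p among falls belonged to Rplp1, Ddit4 and Tmem160, with log2 fold changes of -0.94, -0.92 and -1.04. WT replicate 2 was far from both groups in Rplp1, at 4051 CPM against 323 and 320 in the other wild types, and in Slc39a5, at 24.7 against 3.56 and 3.32. In other genes it lay with the Ash1l+/- libraries or beyond them, at 22.5 CPM for Nts, 2.39 for Ccl2, 5.75 for Mobp, 34.3 for Ddit4 and 0 for Nmur1. None of these genes passed in edgeR with all 6 libraries, and the log2 fold changes included 1.21 for Nts, 0.84 for Ccl2, -0.70 for Nmur1, -0.55 for Ddit4, -3.22 for Slc39a5 and -3.23 for Rplp1. With GC and length trends removed, Slfn9, Ptprq, Mfap4, Pcsk4, Ramp3, Apobr and Nmur1 no longer passed, and the others named here still did. The folds of those that were lost stayed of similar size, such as 1.26 for Slfn9 (adjusted p = 0.0566), -1.73 for Mfap4 (0.051), -1.13 for Ramp3 (0.0537) and -1.05 for Nmur1 (0.101).

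Genes of axon injury and regeneration, a list fixed in advance, were higher as a group. With all 6 libraries edgeR called none of its 20 measured members over all genes and 1 when adjusted over the list alone, while DESeq2 called Atf3 over all genes. The camera set test called the list at an adjusted p of 1.32e-04, with an adjusted p = 0.728 with an estimated correlation. Among the 5 libraries without WT replicate 2, 13 members rose, 1 fell and 6 did not pass (15 rose and 1 fell when adjusted over the list alone), with a median fold of 1.67. The camera adjusted p was 2.29e-06, and the adjusted p was 0.468 with an estimated correlation. The member that fell was the heat shock gene Hspb1. After removal of the GC and length trends 15 members rose and 0 fell (17 and 0 adjusted over the list alone), at a camera adjusted p of 8.63e-12 and an adjusted p of 0.613 with an estimated correlation. Per library, the list's median log2 difference from WT replicates 1 and 3 was 0.36, 1.04 and 0.75 in Ash1l+/- replicates 1, 2 and 3, and 0.67 in WT replicate 2. Gal, the galanin gene, was at 12.6, 17.6 and 14.4 CPM in Ash1l+/-, 9.63 and 9.85 in WT replicates 1 and 3, and 55.1 in WT replicate 2. Its direction turned with that library, from -0.74 with all 6 to 0.61 in the 5.

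**Figure D3:**
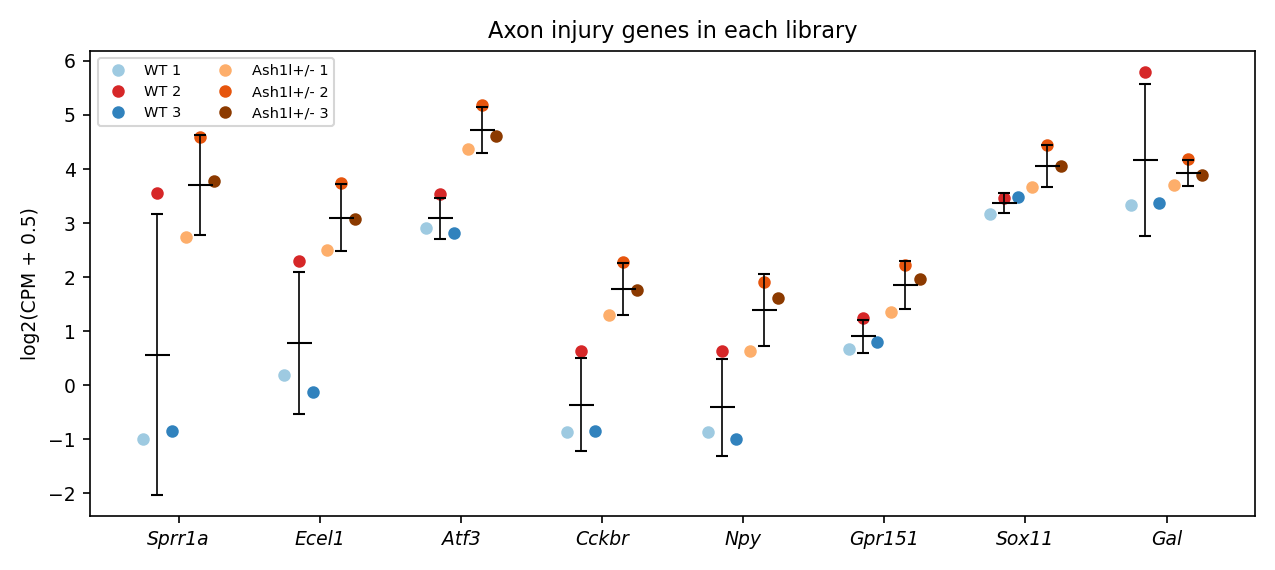
Axon injury genes in each library as log2(CPM + 0.5). Points are single libraries, and dashes and bars are the mean and SD of 3 libraries on that scale. For Sprr1a, WT replicate 2 lies at 11.3 CPM between Ash1l+/- replicates 1 and 3, while WT replicates 1 and 3 are at 0 and 0.0518.

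By camera, interferon response genes were also higher as a group. With all 6 libraries the list was called at an adjusted p of 0.00371 with no member past the threshold in edgeR, over all genes or adjusted over the list alone, and the adjusted p was 0.728 with an estimated correlation. Without WT replicate 3 that call was lost (0.0572). With 5 libraries 7 of 25 members rose and 1 fell (8 and 1 adjusted over the list alone), at an adjusted p of 6.71e-05 by camera and an adjusted p of 0.481 with an estimated correlation. Ifit1, which encodes an RNA-binding antiviral protein, was at 32.6 ± 4.32 CPM in Ash1l+/- against 17.8 and 17.7 in WT replicates 1 and 3 and 41.0 in WT replicate 2 (log2 fold change 0.88, SE 0.12 in the 5 libraries). Zbp1, a nucleic acid sensor, had a log2 fold change of 1.70 (SE 0.46). Ifi27 went down, at -0.56 (SE 0.07). With trends removed 4 members rose and 1 fell (9 and 1 adjusted over the list alone). The adjusted p was then 1.14e-05 by camera and 0.613 with an estimated correlation. By fry the list was not called with 6 libraries (adjusted p = 0.15) or 5 (0.105), nor with trends removed from them (0.191 and 0.167). Its median log2 difference from WT replicates 1 and 3 was 0.61, 0.46 and 0.17 in Ash1l+/- replicates 1, 2 and 3. In WT replicate 2 it was 0.07.

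Hox genes, which mark position along the body axis, included 4 neighbouring Hoxb genes that were lower without WT replicate 2. There 6 of 24 members fell and 0 rose (7 and 0 adjusted over the list alone). They were Hoxb5, Hoxb6, Hoxb7, Hoxb8, Hoxa5 and Hoxd1. Hoxb5 (chromosome 11, 96303336 to 96306121) was at 11.6 ± 1.14 CPM in Ash1l+/- against 22.7, 45.9 and 21.5 in WT replicates 1, 2 and 3, a log2 fold change of -0.93 (SE 0.12) in the 5 libraries and -1.37 (SE 0.33, adjusted p = 0.385) in all 6. Hoxb7 was lower by a log2 fold change of -1.06 (SE 0.20) and Hoxb8 by -0.92 (SE 0.14). The list was called by camera at an adjusted p of 0.00237 in the 5 libraries, with an adjusted p of 0.358 with an estimated correlation, and missed the threshold with all 6 (0.11), in the 5 with trends removed (0.103) and without WT replicates 2 and 3 (0.0661), where the single wild type left was assumed to vary like the other group. With all 6 it was called lower on the filtered FPKM scales and with quality weights. The list was lowest in the wild type left out. Its median log2 difference from WT replicates 1 and 3 was -0.68 in WT replicate 2. It was -0.23, -0.22 and -0.39 in Ash1l+/- replicates 1, 2 and 3. With trends removed these medians were -1.01 in WT replicate 2 and -0.12, -0.14 and -0.20 in the Ash1l+/- replicates. Each of the 6 genes was also called with the trends removed.

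**Figure D4:**
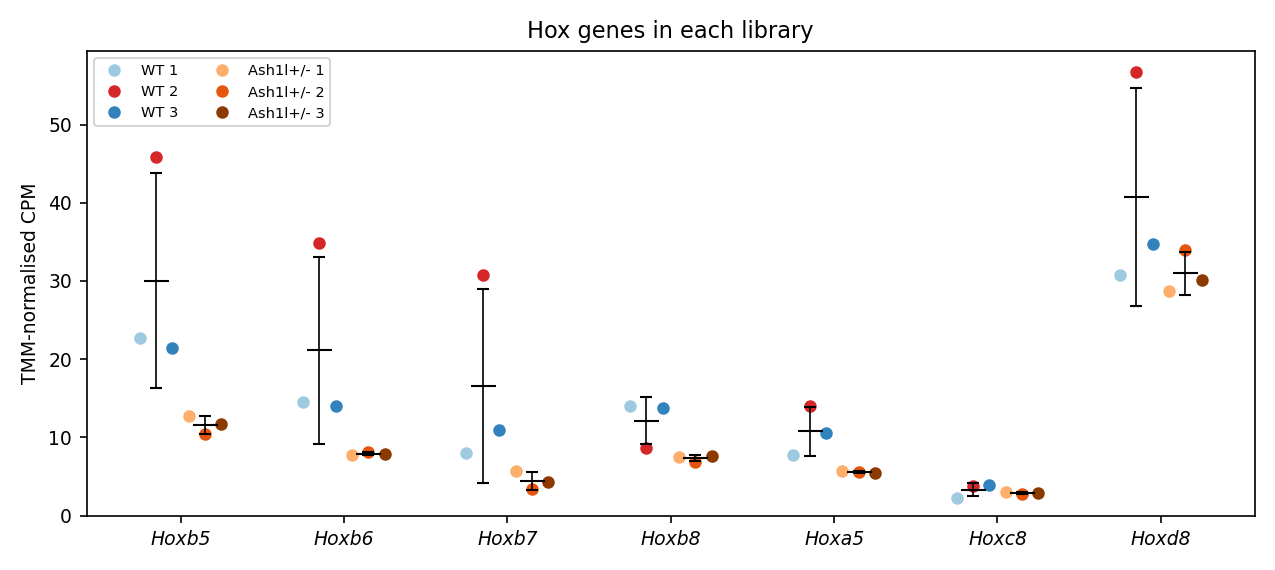
TMM-normalised CPM of Hoxb5 to Hoxb8, Hoxa5, Hoxc8 and Hoxd8 in each library, with the mean and SD of 3 libraries as dashes and bars. The Ash1l+/- libraries lie below all wild types for Hoxb5, at 10.4 to 12.7 CPM against 21.5 to 45.9, and overlap with them for Hoxc8 and Hoxd8.

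Genes of energy metabolism and translation were lower as groups, by an amount that differed with WT replicate 2. With all 6 libraries the median oxidative phosphorylation gene was at 0.367 of the wild-type level and the median cytosolic ribosome gene at 0.338, each with an adjusted p of 9.77e-10 by camera and an adjusted p of 0.81 with an estimated correlation, and with no member past the threshold in edgeR over all genes or adjusted over the list alone. Without WT replicate 2 the medians were 0.862 and 0.86. There 34 of 71 oxidative phosphorylation genes fell and 1 rose (40 and 2 adjusted over the list alone), and 37 of 77 ribosomal genes fell and 6 rose (43 and 7). The adjusted p values were 4.00e-07 and 4.83e-05 by camera, and 0.358 and 0.442 as adjusted p with an estimated correlation. Ndufa2 and Ndufb6, subunits of complex I, had log2 fold changes of -0.86 and -0.85. Rpl21 rose by a log2 fold change of 1.00, Rps27 rose by 0.95 and Rplp1 fell by 0.94; with all 6 libraries, where WT replicate 2 had 594 CPM of Rpl21 and 308 of Rps27, the first 2 stood at -1.77 and -1.56 and missed the threshold. Counts of ribosomal protein genes and Snrpf are uncertain, because reads can be shared with processed pseudogenes. With trends removed the medians were 0.902 and 0.931, with 26 and 22 members lower and 4 and 11 higher, at camera adjusted p of 1.12e-05 and 0.00667 (0.613 and 0.629 as adjusted p with an estimated correlation). The mitochondrial genome list was not called with all 6 libraries (adjusted p = 0.389) or in the 5 (0.552). In the 5 with trends removed, its camera direction turned from higher to lower, still uncalled (adjusted p = 0.0524). There 0 of its 13 members were higher and 4 were lower.

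let-7 targets, chosen because the series title names the microRNA let-7b, were called higher with all 6 libraries (adjusted p = 0.0295, and 0.728 as the adjusted p with an estimated correlation) and in the 5 (0.0173, and 0.358). Without WT replicate 2, 6 of 27 members rose and 2 fell (7 and 2 adjusted over the list alone). The cyclin gene Ccnd2 had a log2 fold change of 0.65 (SE 0.15) and Hmga1, a chromatin architectural protein gene, one of -0.66 (SE 0.10). Genes of H3 lysine 36 and Polycomb-Trithorax chromatin were called at adjusted p of 0.0127 with 6 libraries and 0.0368 with 5 (0.81 and 0.358 as adjusted p with an estimated correlation), with 8 of 32 members higher and 1 lower in the 5 (10 and 1 adjusted over the list alone). Setd2 and Kmt2c, both histone methyltransferase genes, had log2 fold changes of 0.49 and 0.48. Leaving out 1 more library ended the 5-library chromatin call without WT replicate 3 (adjusted p = 0.155, with a single wild type left) and without Ash1l+/- replicate 2 (0.0773). The 6-library let-7 call was lost without WT replicate 1 or WT replicate 3 (adjusted p up to 0.0737). Voltage-gated channel genes were called with 6 libraries (adjusted p = 0.0429, and 0.81 with an estimated correlation) and neither with 5 (0.253) nor without Ash1l+/- replicate 1 (0.0633). The 6-library call was also lost in 9 of 19 other settings, and with the GC trend alone removed from the 5 libraries the list was called higher (adjusted p = 0.00591). In the 5, 12 of 45 members rose and 9 fell (15 and 10 adjusted over the list alone). No member of these 3 lists passed in edgeR with 6 libraries, over all genes or adjusted over the list alone. With both trends removed from the 5 libraries, the let-7 target and chromatin lists were no longer called (adjusted p = 0.198 and 0.191) and the channel list stayed uncalled (0.331). Then 3 let-7 targets were higher and 1 lower, 1 chromatin gene was higher and 1 lower, and 1 channel gene was higher and 0 lower. Over all 16395 genes tested in the 5 libraries, 3252 were called before and 1184 after that removal. With both trends removed from all 6 libraries none of the 3 was called (0.579 for let-7 targets, 0.2 for chromatin and 0.179 for channels). The microRNA processing list missed the threshold by camera in both comparisons (0.06 and 0.0662). It was called higher by fry in the 5 libraries (adjusted p = 0.0317), with 5 of 18 members higher and 0 lower. Among those higher were Ago3 at a log2 fold change of 0.47 and Tut7 at 0.42. With both trends removed from the 5 libraries, 0 members were higher and 1 was lower. The list was then called neither by camera (adjusted p = 0.953) nor by fry (adjusted p = 0.707).

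Sensory neuron subtype lists were not called by camera, and fry called the cold-sensing list higher in the 5 libraries (adjusted p = 0.0428). That list was lower, uncalled, with all 6 libraries (fry adjusted p = 0.467) and in the 5 with both trends removed (0.85). With 5 libraries, 5 of 15 peptidergic nociceptor genes rose and 2 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.322). Oprm1, the mu opioid receptor gene, had a log2 fold change of 0.97 (SE 0.17) and Smr2 one of 0.69 (SE 0.21). Of 15 non-peptidergic genes 1 rose and 2 fell (adjusted p = 0.715), and of 16 itch neuron genes 2 rose, among them Nts, and 1 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.322). In the mechanoreceptor and proprioceptor list 7 of 18 rose and 0 fell (0.253), with Ntrk3, a neurotrophin receptor gene, at a log2 fold change of 0.46 (SE 0.08). Among 6 cold-sensing genes Trpm8, a cold-activated channel gene, rose by 0.53 (SE 0.10), and the list had an adjusted p of 0.406. The same lists had adjusted p with all 6 libraries of 0.269, 0.167, 0.804, 0.616 and 0.895 in the same order. WT replicate 2 was low in Oprm1 and Trpm8, at 0.224 and 1.12 CPM.

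The remaining functional lists were called by camera neither with all 6 libraries nor with 5. Their adjusted p with 6 and 5 libraries were 0.578 and 0.253 for immediate early genes, 0.895 and 0.892 for extracellular vesicle release, 0.895 and 0.988 for synaptic release machinery, 0.578 and 0.468 for cytokine and innate sensing genes, 0.81 and 0.253 for cholesterol synthesis, and 0.895 and 0.651 for dissociation and heat stress. Single members still passed in the 5 libraries, such as Pclo, a presynaptic scaffold gene, at a log2 fold change of 0.53, and Tm7sf2, a sterol reductase gene, at -0.57.

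No cell type marker list was called by camera with all 6 libraries or with 5. Sensory neuron markers had an adjusted p of 0.965 with 6 libraries and 0.911 with 5, and satellite glia 0.913 and 0.481, with Cdh19, a cadherin gene of glia, at a log2 fold change of 0.47 in the 5. Myelinating Schwann cell markers gave 0.511 and 0.911, non-myelinating Schwann cell markers 0.511 and 0.527, endothelial cell 0.965 and 0.809, mural cell 0.965 and 0.896, and macrophage 0.382 and 0.527. Lymphocyte markers gave 0.516 and 0.529, neutrophil and mast cell 0.0632 and 0.527, erythrocyte 0.0632 and 0.481, and central nervous system tissue 0.642 and 0.911. Skeletal muscle gave 0.201 and 0.527, adipocyte 0.362 and 0.481, bone and cartilage 0.571 and 0.679, and dividing cell 0.241 and 0.481. The fibroblast list had an adjusted p of 0.202 with 6 libraries and 0.198 with 5, and was called lower with trends removed from the 5 (adjusted p = 0.00428, and 0.942 as the adjusted p with an estimated correlation) and from the 6 (0.0499, and 0.61). It was also called lower with the GC trend alone removed from either, without Ash1l+/- replicate 2 in either (adjusted p = 0.0279 with the other 5 libraries and 0.0118 when WT replicate 2 was left out too), and, from the 5, without WT replicate 3 and with a replicate block. Without WT replicate 2, 5 of its 13 members fell and 1 rose, with Fbln1, Pi16 and the collagen gene Col1a1 at log2 fold changes of -1.06, -1.03 and -0.63.

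No excess of changed genes was detected around Ash1l. Within 10 Mb of it, 0 of 254 genes had an unadjusted p under 0.01 with all 6 libraries, against 0.78% of the other genes (Fisher's exact test, two-sided, p = 0.271). With 5 libraries 36 of 259 passed the adjusted threshold, or 13.9%, a lower share than the 19.9% of other genes (p = 0.0147 by Fisher's exact test). With trends removed the shares were 7.34% and 7.22% (p = 0.904, Fisher's exact test). Within 5 Mb, with trends removed from the 5 libraries, they were 10.4% and 7.2% (p = 0.176, Fisher's exact test). Only 123 of 16032 genes had an unadjusted p under 0.01 with all 6 libraries, so that test could miss a small excess. Sprr1a lies within the 10 Mb window.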

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

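Tests with trends removed, with quality weights and all variants of the 5-library comparison were chosen after seeing the data. The number of changed genes depended on WT replicate 2. With all 6 libraries edgeR gave 0 genes, and 0 under RLE, upper-quartile and total scaling, both count filters, limma-voom, the FPKM scales, both gene subsets, an adjusted threshold of 0.1 and each trend removal. DESeq2 gave 3, voom with library quality weights (0.0274 for WT replicate 2) gave 4179, unadjusted p of 0.05 and 0.01 gave 1702 and 123, and leaving out 1 library gave 0 to 3252. The upper value is the fit without WT replicate 2. In the 5 libraries 3252 genes became 1402 on log2(FPKM + 1), 1399 on log2(FPKM + 0.1), 0 on log2(FPKM + 1) with no filter, 1595 with the GC trend removed, 1184 with GC and length removed and 5440 at an unadjusted p of 0.05. Leaving out 1 more library gave 796 (without WT replicate 1) to 4198, with 1855 and 2120 without Ash1l+/- replicates 2 and 3. Without WT replicate 1 or 3, these fits have a lone wild type assumed to vary like the other group. The cause was not tested.

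The camera count of functional lists was 7 with 6 libraries and 7 with 5. It fell to 4 in both with GC and length removed and to 0 in both with an estimated correlation, and fry called 0 with 6. Leave-one-out fits gave 5 to 8 lists in both. Marker lists called with 6 libraries went from 0 to 2 with upper-quartile factors, 2 with library totals, 5 with no count filter, 4 with DESeq2, 3 on unfiltered FPKM, 3 with the GC trend removed, 1 with GC and length removed and 0 to 5 in leave-one-out fits. With 5 libraries they went from 0 to 1 with the GC trend removed, 1 with GC and length removed and 0 to 3 when leaving out a library. Library totals alone shifted the median gene by 0.13 with 6 libraries.

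Ash1l stayed short of the threshold with 6 libraries, from 0.22 to 0.66 in leave-one-out fits, and its sign turned to -0.0374 with GC and length removed. In the 5 libraries it was 0.23 with quality weights (adjusted p = 0.0459), 0.14 to 0.30 when leaving out a library, past the threshold without Ash1l+/- replicate 1 (0.23, adjusted p = 0.0476), -0.00448 with the length trend removed and -0.0345 with GC and length removed. Adjusted p over its 5-library alternatives ran from 0.0248 to 0.978.

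Deviations of same-numbered libraries from their group means correlated at 0.000517, -0.0317 and 0.0378. Of the 3 numbers only number 3 correlated best with itself. The wild-type mean included WT replicate 2, whose distance enters every wild-type deviation. These correlations therefore cannot tell whether the replicate numbers pair the samples. With the replicate block edgeR called 0 genes with 6 libraries and 3982 with 5, 2 marker lists with 6 and 2 with 5, Ash1l at 0.24 with 5 (adjusted p = 0.0248), and 20.1% of genes within 10 Mb of Ash1l with 5.

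Within 10 Mb of Ash1l, shares are at an unadjusted p under 0.01 where fewer than 20 genes passed the adjusted threshold, and at the adjusted threshold otherwise. At the unadjusted p the share was 0% with 6 libraries, 0.239% with DESeq2, 0.473% on unfiltered FPKM, 0% in 4 leave-one-out fits and, with the direction turned, 0.385% without Ash1l+/- replicate 3. At the adjusted threshold it was 18.5% with quality weights and 13.9% without WT replicate 2. For those 5 libraries the difference from other genes was lost with upper-quartile factors (15.4%), no count filter (9.55%), DESeq2 (7.16%), unfiltered FPKM (5.49%), protein-coding genes (17.3%), the GC trend removed (9.27%), quality weights (20.1%), a 5 Mb window (17.2%), the replicate block (20.1%), without WT replicate 1 (2.94%) and without Ash1l+/- replicate 2 (9.34%), and turned with GC and length removed (7.34%). Leave-one-out shares ran from 2.94% to 20.3%. The Hox list turned upward, uncalled, with GC and length removed from 6 libraries (adjusted p = 0.919) and was called lower in 3 other settings (lowest 0.00358), and the voltage-gated channel list turned downward, uncalled, with length removed from 5 (0.604) and was called higher with GC removed (0.00591). Other settings than leaving out a library ended the 6-library call in 9 of 19 for channels, 7 for let-7 targets and 4 for chromatin, and the 5-library call in 5 for let-7 targets and 4 for chromatin. Of 20 genes selected by the naming rule with 6 libraries and 34 with 5, 0 changed direction, but in 99 of 714 comparisons with 5 libraries the call was lost, for Pik3r6 in 5 of 5 leave-one-out fits, for Ptprq and Pcsk4 in 4 of 5 and for Apobr and Zkscan16 in 3 of 5. Library totals are alike, and simulated 2-fold changes were recovered in 0% of cases with the spread of 6 libraries and 87% with that of 5.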

Other observations

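All tests here were chosen after the results were seen, except the counts over other splits of the libraries. With trends removed from the 5 libraries, 4 single genes not described so far also differed, while the erythrocyte and sensory neuron lists were not called (adjusted p = 0.331 and 0.605) and the fibroblast list was called lower by camera (0.00428, and 0.942 as the adjusted p with an estimated correlation). Eln, the elastin gene, was at 5.88 CPM on average in Ash1l+/- and 13.2 in WT replicates 1 and 3, with a log2 fold change of -0.98 and an adjusted p of 0.000704 (edgeR). Hbb-bt, a hemoglobin gene, had a log2 fold change of -1.05 and stood at 25.2 CPM in WT replicate 2. Its call in the 5 libraries was lost in 4 of 17 settings other than leaving out a library. Gfra3, the artemin receptor gene of nociceptors, rose by 0.69, and Nefh, the heavy neurofilament gene, rose by 0.49 in the same fit. With all 6 libraries the last 2 stood at 0.10 and 0.06 and missed the threshold, WT replicate 2 having 67.1 CPM of Gfra3 and 3472 of Nefh.

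WT replicate 2 stood apart from the other 5 libraries. GC and length trends as fitted are argued against as the whole cause. With both removed, its highest correlation with another library was 0.897, below the lowest of 0.986 among the others. After removal the 6-library fold changes kept a rho of 0.092 with gene length, so trends beyond the fitted curves stay open. Skeletal muscle is argued against too, since 12 muscle genes took 0.00304% of the counts of WT replicate 2. The median of that list was still 3.18 above the other wild types. A lower recovery of long transcripts may be part of the cause, with a rho of -0.45 against gene length when ribosomal and oxidative phosphorylation genes are left out, compared with -0.0858 between WT replicates 1 and 3. WT replicate 2 carries the same label as the other wild types, and the labels name no biological difference between them. Apart from skeletal muscle, no biological difference was tested as a cause.

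The rise of axon injury genes in the libraries labelled Ash1l+/- does not reduce to the GC and length trend, as 15 of 20 members were called higher in the 5 libraries after its removal. More neurons in those samples are argued against by a median log2 fold change of 0.0688 in sensory neuron markers, against 0.63 for the injury list. The median absolute deviation of the markers, scaled to match an SD for normal data, was 0.174. Nerve injury of single animals, unrelated to genotype, could produce the same pattern and cannot be told apart from genotype with 3 libraries a group. WT replicate 2 showed the list at 0.668 above the other wild types, more than Ash1l+/- replicate 1 at 0.36, and at 0.39 against 0.46 with trends removed. The genotype remains an open and untested explanation.

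Hoxb5 to Hoxb8 were lower in the libraries labelled Ash1l+/-. All 4 stayed called in the 5 libraries with the GC and length trend removed, at a median log2 fold change of -0.769 (-0.92 before), which argues against that trend as the whole cause. Ganglia taken from another body level, lowering groups 5 to 8 of every cluster, are argued against by 7 paralogs of these groups in the other clusters. Their median was 0.00497, with a median absolute deviation, scaled in the same way, of 0.177, and 1 of them, Hoxa5, was called lower. A narrower difference in body level stays open, and the genotype is an open and untested explanation.

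Other splits of the libraries were too few to reach a share under 0.05. With 6 libraries all 10 splits gave 0 genes, the real value being 0 and the highest other 0. For functional lists 2 of 10 splits gave as many as the real 7, the highest other was 7 and the lowest was 3. With 5 libraries the real split gave 3252 genes and the highest of the other 9 gave 12, with 1 of 10 splits as large. For lists the real split gave 7, the highest other 6 and the lowest 1, and 1 of 10 was as large. Camera with the preset correlation therefore called lists under every split of these libraries, so a call alone does not set the genotypes apart.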
